A study of Rattus norvegicus with 145 samples.

How the data were processed

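Libraries were assigned to genotype, region, age and sex from the submitters' labels, and to animals from the identifiers in the sample descriptions. Per the labels' protocols, tissue was flash frozen, total RNA was extracted with a Qiagen kit, RNA integrity was followed on a Bioanalyzer, and libraries were made with standard Illumina protocols. The deposited count table held estimated counts, with 8.12% of cells not whole, for 32883 Ensembl rat gene identifiers, and its values were rounded to whole numbers here. The second deposited table is named FPKM by the authors, but each library summed to 1000000, so its values are on the TPM scale and were treated as TPM. The reference is named Rat.B6.0, per the file headers; the aligner, the counting tool and the annotation release are not given in the sources used here. All columns of both tables were matched to samples by the animal and region in their names. The design fixed before the data were examined assumed whole counts.

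The files do not pair identifiers with symbols, and 0 of 32883 identifiers matched the gene table used here. The 33 gene lists and cell type markers fixed before the data were examined were therefore not tested here. The targeted huntingtin gene could not be picked out by name. Which identifier is its own, and whether it is among those printed below, is not known here. The rule for named genes, fixed at the same time, took genes past the threshold that have a symbol, a mean log2 CPM of at least 1 and the same sign in both sexes, ordered by p. Without the symbol condition, 2 identifiers that rose and 2 that fell are printed from the first 2 in each direction of the genotype comparisons; which of them to print was decided after their values were seen.

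Each genotype comparison was fitted on the libraries of 1 region and 1 age with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust quasi-likelihood F test), with sex as a covariate where both sexes were present. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Sex by genotype was a contrast averaged over ages, age by genotype a difference of differences between ages, and region by genotype a difference within animals. Ages were compared in WT animals with sex as a covariate. Animals were separate, so p-values measure spread between animals. Levels are CPM with TMM factors, and errors are the SD over animals or the SE of the log2 difference.

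Added after the data were seen were the average over ages, cortex against cerebellum, the overlap of cerebellar calls, and region-enriched gene groups. The groups were defined in WT libraries of 24 months to test the other ages, and in those of 19 months to test 24 months, so no library was used for both. They held 216, 216 and 359 genes for striatum, cortex and cerebellum from the first and 277, 210 and 342 from the second. Groups were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and with an estimated one, adjusted over 30 tests, and by an exact permutation test of their mean per library.

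Alternatives were RLE size factors, DESeq2 1.42.0, no count filter and a strict filter of 1 CPM, all ages of a region in 1 fit, limma-trend on log2 of the TPM-scale values plus 0.1 or 1, with genes of a mean of at least 0.1 or without that filter, replicate number as a block, no sex term, each sex alone, and leaving out each library in turn at 2, 6 and 24 months. Added later were fits without libraries of outlying correlation, with each library's slope on effective transcript length as a covariate, and with a score of cortex-enriched genes as a covariate, and for the region-enriched groups at 24 months fits without each library and, in striatum, without the 2 of highest cortex score. A library was taken as outlying where its mean Spearman correlation with its region and age lay more than 5 scaled median absolute deviations below the median; 9 libraries were, 4 KI and 5 WT. Effective length was taken from the ratio of the 2 deposited tables.

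The fits were tested on simulated data with 200 changed genes before the real data. Simulated genes were drawn independently of each other, without structure that libraries share across genes. The counts of recovered genes and false calls hold for that setting, and do not show how many changes the real data could reveal. For KI against WT in cerebellum at 19 months, on 15101 genes, edgeR recovered 97 of 100 genes changed by 1 log2 unit and 82 of 100 changed by 0.5, with 11 false calls among 190. For cortex at 19 months, on 15280 genes, it recovered 99 and 91, for striatum at 19 months, on 15271 genes, 92 and 71, and for striatum at 24 months, on 15645 genes, 66 and 11. DESeq2 made more false calls on the same data. It made 29 among 215 for cerebellum at 19 months, 43 among 216 for striatum at 19 months and 60 among 226 for cortex at 24 months. Sex labels were checked with the 2 female-biased and 5 male-biased genes that separated the sexes in WT cortex at 10 months, and 135 of 135 other libraries matched. No 2 libraries of a group differed by as little as counting noise: the smallest ratio of the squared difference to its counting expectation was 6.01.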

Results

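Messenger RNA was profiled by bulk RNA sequencing in 3 brain regions of a rat model of Huntington's disease. The animals were heterozygous for a Q130 knock-in (KI) or were wild type (WT). Huntington's disease is caused by an expanded CAG repeat in the huntingtin gene, and the striatum is the region of the brain that degenerates most. Striatum was sampled at 2, 6, 10, 19 and 24 months of age, cerebral cortex at 10, 19 and 24 months, and cerebellum at 19 and 24 months, giving 63, 51 and 31 libraries. At 10 and 19 months each genotype had 5 females and 5 males. At 24 months there were 3 female and 4 male KI animals and 2 female and 2 male WT animals. The 2-month and 6-month striatum libraries came from 3 males per genotype and were added by the submitters as pipeline controls from earlier work. The libraries came from 63 animals, of which 51 were sampled in more than 1 region. Total estimated counts per library, in units of 1000000, ran from 26.7 to 34.5 in striatum, from 28.9 to 47.3 in cortex and from 25.6 to 34.4 in cerebellum. Genes carry Ensembl identifiers that the files do not pair with symbols, so genes are described below by identifier, as counts, and as groups defined by the region in which they were highest.

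The KI cerebellum differed from the WT cerebellum at both ages sampled. At 19 months 352 of 15101 genes tested differed, with 158 higher and 194 lower in KI (n = 10 per genotype, edgeR, adjusted p under 0.05). At 24 months 334 of 15381 genes differed, with 185 higher and 149 lower (7 KI and 4 WT animals). Most changes were small: the median absolute log2 difference of the genes called was 0.29 at 19 months and 0.36 at 24 months, and 13 and 20 genes passed a 2-fold change. Of these, 10 rose and 3 fell at 19 months, and 15 rose and 5 fell at 24 months. With DESeq2 the counts were 548 and 668. On simulated data DESeq2 made more false calls than edgeR here, 29 among 215 against 11 among 190 at 19 months. At 24 months these were 39 among 221 and 6 among 169. Within 1 sex at a time fewer genes passed, 77 in females and 8 in males at 19 months, and 27 and 60 at 24 months. The 24-month count fell to 115 without the WT male M2, to 142 without WT male M1, to 143 without WT female F1 and to 210 without KI male M4.

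The identifier ENSRNOG00000017456 rose most clearly in KI cerebellum. Its level was 2.45 ± 0.525 CPM in WT and 7.73 ± 1.61 CPM in KI at 19 months (SD, n = 10 each), a log2 difference of 1.64 ± 0.137 (SE; edgeR adjusted p = 2.45e-07). At 24 months it was 2.53 ± 0.195 CPM in WT (SD, n = 4) and 8.86 ± 1.11 CPM in KI (SD, n = 7), a log2 difference of 1.81 ± 0.112 (SE; edgeR adjusted p = 7.12e-06). The lowest KI library lay above the highest WT library at both ages, at 4.52 against 3.68 CPM and at 7.58 against 2.8 CPM. In males alone at 19 months its adjusted p was 0.0563 with edgeR, with a log2 difference of 1.43. In WT cortex the same gene stood at 27.6 ± 2.16 CPM and in WT striatum at 11.3 ± 1.19 CPM at 19 months (SD, n = 10), so its mean KI cerebellar level remained below that of both forebrain regions at that age. At 24 months it stood at 25.6 ± 1.41 CPM in WT cortex and 9.01 ± 1.26 CPM in WT striatum (SD, n = 4). The KI cerebellar libraries, from 7.58 to 10.1 CPM, then lay within the WT striatal range of 7.24 to 10.2 CPM. The identifier ENSRNOG00000034102 fell in KI cerebellum. It went from 70 ± 10.7 CPM in WT to 33.4 ± 4.79 CPM in KI at 19 months (SD, n = 10), a log2 difference of -1.06 ± 0.0795 (SE; edgeR adjusted p = 7.92e-08), and from 64.5 ± 5.99 (n = 4) to 34 ± 3.86 CPM (n = 7) at 24 months, a log2 difference of -0.95 ± 0.0727 (SE; edgeR adjusted p = 4.77e-05).

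**Figure D1:**
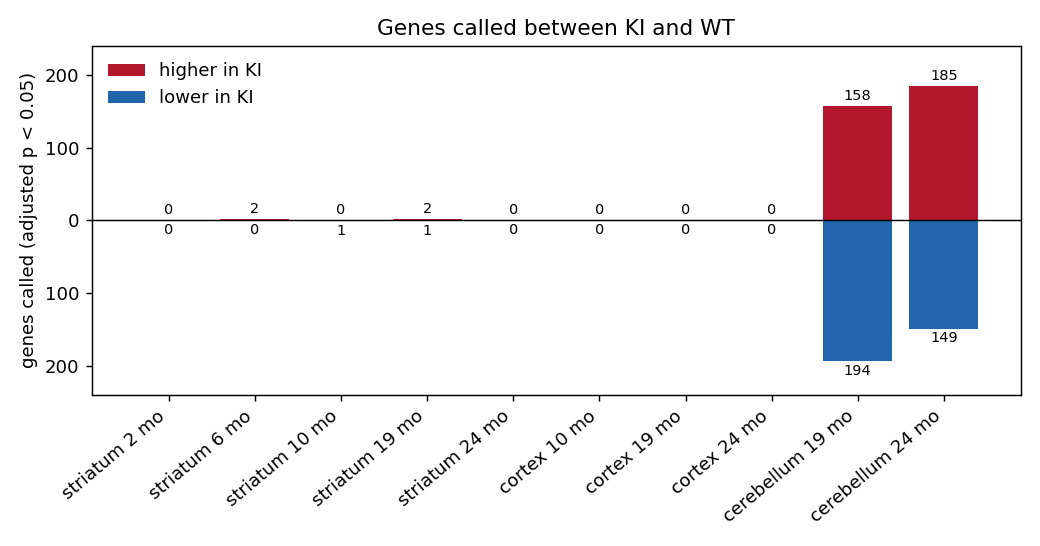
Genes called between KI and WT (edgeR, adjusted p under 0.05) for each region and age, as bars above 0 for genes higher in KI and below 0 for genes lower in KI. The cerebellar bars reach 158 and 185 genes higher and 194 and 149 lower, against at most 3 genes in any striatal or cortical comparison.

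The cerebellar changes recurred at the later age in different animals. The calls at the 2 ages shared 139 genes, 61 that rose at both and 78 that fell at both, where independent lists would share 1.93 and 1.92 (Fisher's exact test, p = 5.02e-78 and p = 1.45e-112, across genes, which are not independent replicates). No gene was called in opposite directions. Of the 158 genes that rose at 19 months 156 were also higher in KI at 24 months, and of the 194 that fell 191 were also lower. The shared genes had median absolute log2 differences of 0.38 at 19 months and 0.45 at 24 months, and 106 of the 139 had the larger difference at 24 months. Being called at 24 months, with fewer animals, favours large values there. Risers and fallers called at 19 months had medians of 0.343 and -0.278 then, and 0.321 and -0.256 at 24 months. Those called at 24 months had 0.374 and -0.339 then, and 0.2 and -0.237 at 19 months. No change with age is read from these values. The overlap was not part of the planned comparisons and was tested after the counts were seen.

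**Figure D2:**
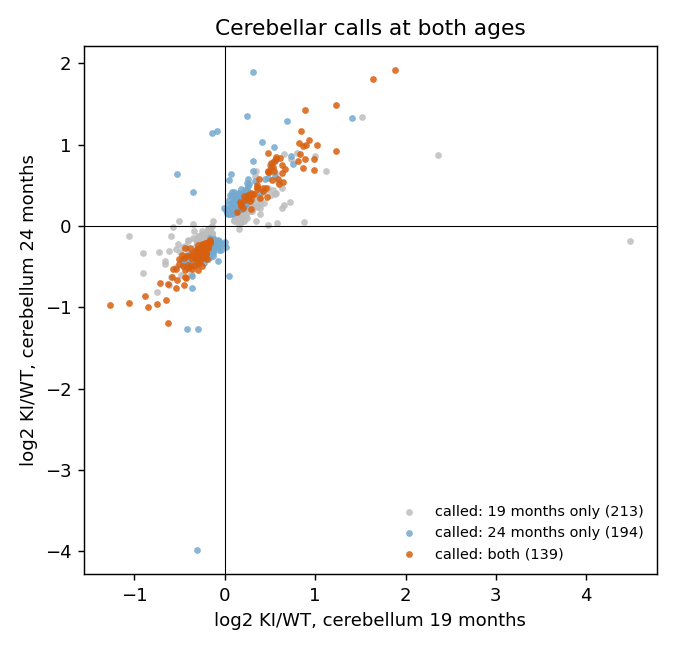
Log2 KI/WT in cerebellum at 19 months (horizontal) and 24 months (vertical) for the 546 genes called at either age and tested at both, each point a gene. The 139 genes called at both ages (orange) lie in the quadrants of equal sign.

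The genes that fell in KI cerebellum were mostly those that the cerebellum expresses above the forebrain. Genes at least 4-fold higher in 1 region than in both others, in WT libraries of another age, were taken as region-enriched; these groups were defined after the data were seen. At 19 months 41 of 356 cerebellum-enriched genes fell and 9 rose, and at 24 months 43 of 342 fell and 5 rose. Adjusted over each group alone, 65 fell and 11 rose at 19 months, and 74 fell and 8 rose at 24 months. The median log2 difference of the group was -0.07 at 19 months and -0.10 at 24 months. With an estimated correlation between genes the camera adjusted p of the group was 0.183 at 19 months and 0.011 at 24 months, over 30 tests of groups. With the preset correlation it was 2.76e-07 and 2.54e-09. Averaged per library, KI minus WT was -0.026 at 19 months and -0.151 at 24 months. The exact permutation test gave 2-sided p = 0.663 and p = 0.0121, and adjusted p = 0.84 and p = 0.318. Of 106 cortex-enriched genes detected in cerebellum at 19 months 5 rose and 0 fell, and of 126 striatum-enriched genes 5 rose and 0 fell. At 24 months the numbers were 7 and 0 of 120, and 7 and 0 of 173. The median log2 difference of the cortex-enriched genes was 0.0423 at 19 months and 0.0763 at 24 months. That of the striatum-enriched genes changed sign, from 0.128 to -0.0568. Among all calls with a WT value in all 3 regions, 93 of 156 risers at 19 months were lower in WT cerebellum than in WT forebrain, against 26 of 194 fallers (Fisher's exact test, p = 5.91e-20) and 6825 of 14677 genes not called. At 24 months these were 126 of 185, 17 of 147 (Fisher's exact test, p = 7.73e-27) and 7285 of 14822. Both tests run across genes, which are not independent replicates, and the fallers lay farther from the genes not called than the risers did.

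In KI striatum at most 3 genes passed edgeR's threshold at any age when each age was fitted alone with all its libraries. At 10 months 1 gene fell among 15284 tested (n = 10 per genotype, edgeR), and at 19 months 2 rose and 1 fell among 15271; DESeq2 called 2 and 5. With all striatum libraries in 1 fit 81 genes were called at 10 months, of which 9 rose and 72 fell. At 24 months 0 of 15645 genes passed with edgeR, with 468 at an unadjusted p under 0.05 where chance gives 782; DESeq2 called 2 and limma-trend 0. At 2 months 0 of 15407 genes passed with edgeR (n = 3 per genotype), with 958 at an unadjusted p under 0.05 where chance gives 770; DESeq2 called 15 and limma-trend 0. At 6 months 2 genes rose with edgeR; DESeq2 called 105, of which 0 were among these. The gene with the smaller p of that pair stood at 5.09 ± 0.244 CPM in KI and 0.201 ± 0.00582 CPM in WT at 6 months (SD, n = 3). It was above 1 CPM in 20 of 74 KI and 15 of 65 WT libraries at the other ages and regions. The 6-month count was 199 without WT male M1, 4 without KI male M1 or WT male M2, and 1 without KI male M2 or M3. Each library's deviation from the 6-month mean was correlated with effective transcript length. Spearman rho was 0.124, 0.342 and 0.328 in KI M1, M2 and M3, and 0.236, -0.408 and -0.205 in WT M1, M2 and M3. Without WT M1 genotype and the length trend cannot be told apart, so the 199 genes are not read as a genotype effect. The 2-month count was 36 without KI male M3, 3 without KI male M2, 2 without WT male M1 and 1 without WT male M2 or M3.

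The gene that fell at 10 and at 19 months was the same one, ENSRNOG00000011073. In striatum it went from 137 ± 12.3 to 99.2 ± 10.4 CPM at 10 months (SD, n = 10; log2 difference -0.46 ± 0.0626 SE, edgeR adjusted p = 0.00655) and from 135 ± 12.7 to 92.3 ± 15.1 CPM at 19 months (SD, n = 10; log2 difference -0.55 ± 0.0884 SE, edgeR adjusted p = 0.0247). Of the 2 genes that rose at 19 months ENSRNOG00000023148 had the smaller p, at 41.1 ± 4.77 CPM in WT and 62.2 ± 9.81 CPM in KI (SD, n = 10), a log2 difference of 0.60 ± 0.0876 (SE; edgeR adjusted p = 0.0152). The lowest KI library, at 49.6 CPM, lay above the highest WT library, at 48.7 CPM. Its WT and KI means were 51.5 ± 11.9 and 50.8 ± 11.2 CPM at 10 months (SD, n = 10) and 42.8 ± 4.06 and 72.2 ± 17.1 CPM at 24 months (SD, n = 4 and n = 7), where it did not pass. The calls at 10 and 19 months were lost with limma-trend on the length-scaled values, which gave 0 at both ages.

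At 24 months the striatum-enriched genes had mostly lower and the cortex-enriched genes mostly higher values in KI striatum, though no member of either group passed edgeR's threshold over all genes. The median log2 difference was -0.44 over 277 striatum-enriched genes, of which 247 were below 0, and 0.34 over 141 cortex-enriched genes. Averaged per library, the striatum-enriched genes stood at 2.42 ± 0.338 in KI and 2.81 ± 0.191 in WT (mean log2 CPM, SD, n = 7 and n = 4; exact permutation test, 2-sided p = 0.0697 over 330 splits). The estimated-correlation camera adjusted p was 0.349 for both groups. The KI libraries M1 and M2 had the highest mean log2 CPM of cortex-enriched genes, at 1.81 and 2.27, against 1.18 in the highest WT library. Without these 2 libraries the median log2 difference was 0.05 for the cortex-enriched genes and -0.28 for the striatum-enriched genes. The cortex-enriched median was 0.20 without KI M2 alone and 0.21 without WT M1 alone. At 10 and 19 months the medians of the striatum-enriched genes were -0.07 and -0.08 and neither group passed with an estimated correlation, with adjusted p = 0.349 for each. With the preset correlation the camera adjusted p was 3.14e-05 and 7.72e-07 for the striatum-enriched genes, and 0.00775 and 7.37e-05 for the cortex-enriched genes. Averaged per library, the striatum-enriched genes stood at 2.77 ± 0.294 in KI and 3 ± 0.252 in WT at 10 months, a difference of -0.23 (SD, n = 10; permutation test, 2-sided p = 0.0808, adjusted p = 0.529), and at 3.02 ± 0.237 and 3.12 ± 0.177 at 19 months.

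**Figure D3:**
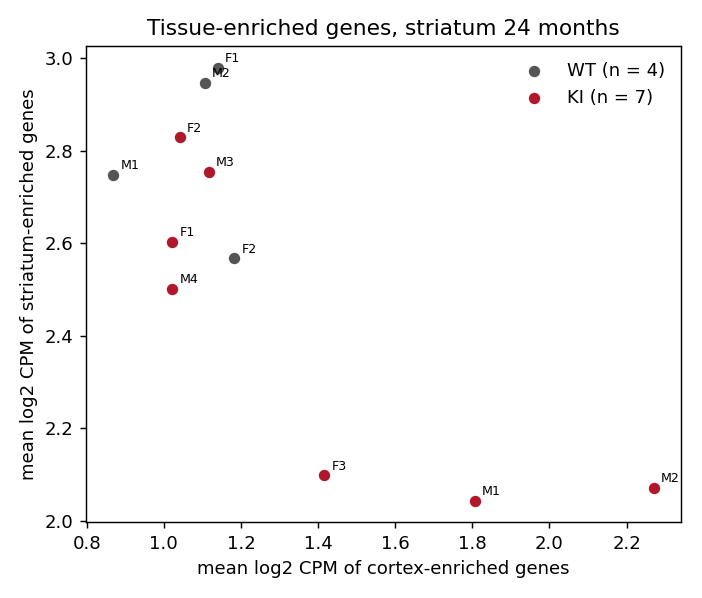
Mean log2 CPM of striatum-enriched genes against that of cortex-enriched genes in the 11 striatum libraries of 24 months, each point a library. The KI libraries F3, M1 and M2 lie lowest on the vertical axis, at 2.099, 2.044 and 2.072, and M2 reaches 2.27 on the horizontal axis.

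In cortex 0 genes passed at each of the 3 ages with edgeR. At 10 months 1013 of 15211 genes had an unadjusted p under 0.05 where chance gives 761, at 19 months 813 of 15280 where chance gives 764, and at 24 months 772 of 15437 where chance gives 772. DESeq2 called 17, 0 and 4 genes, and limma-trend 0 at each age. The region-enriched groups had median log2 differences between -0.055 and 0.0484 in cortex at the 3 ages.

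ENSRNOG00000011073 had a lower mean in KI than in WT in all 10 comparisons of genotype. It passed edgeR's threshold in striatum at 10 and 19 months and in cerebellum at 19 and 24 months, where it stood at 70.3% and 72.2% of WT (edgeR adjusted p = 0.00103 and p = 0.000696). In the 6 others its KI level ran from 61.1% of WT in cortex at 24 months to 87.9% in striatum at 6 months. Averaged over 10, 19 and 24 months in striatum and cortex and over 19 and 24 months in cerebellum, a comparison added after the data were seen, it fell to 68.7% of WT in striatum, 76.4% in cortex and 71.1% in cerebellum (edgeR adjusted p = 1.65e-09, p = 0.0103 and p = 8.01e-07). It was singled out after its values were seen. None of the 15 tests of whether its genotype difference changed with sex, age or region passed edgeR's threshold, and the smallest of the adjusted p was 0.427. Averaging over ages called 4 genes in striatum, 5 in cortex and 1056 in cerebellum, the last with 563 higher and 493 lower in KI.

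**Figure D4:**
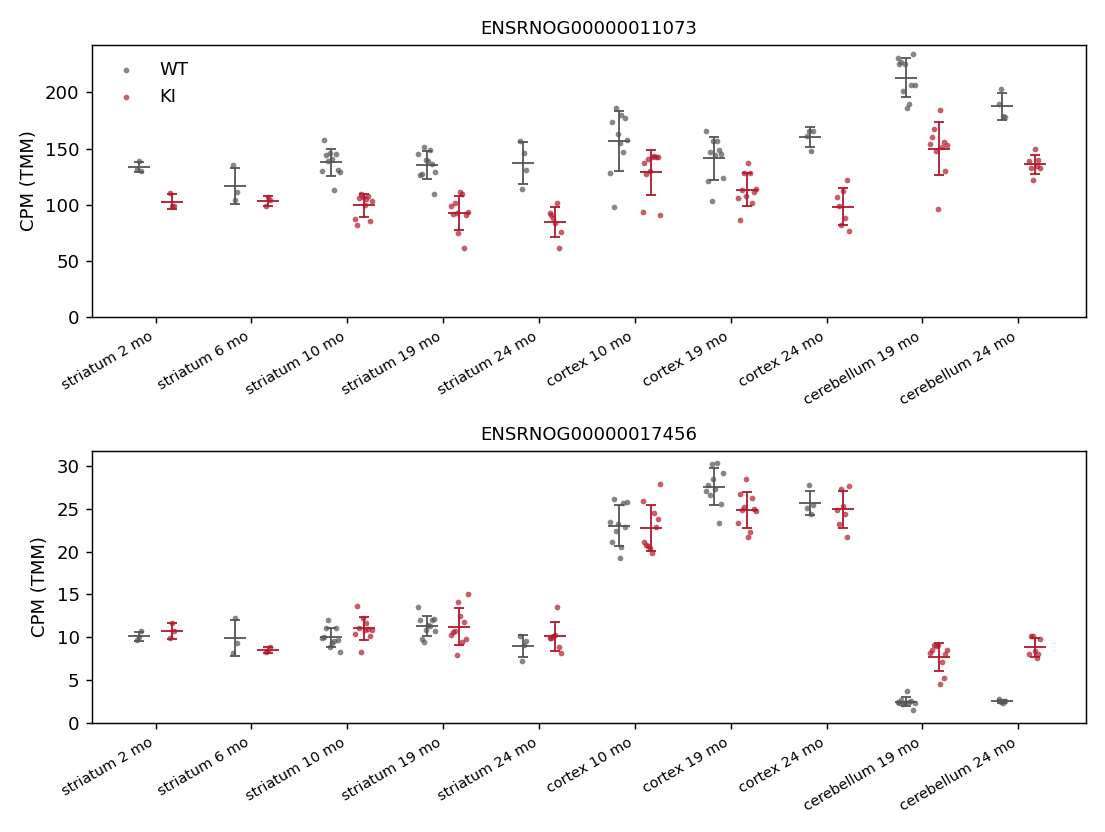
Normalised level (CPM) of ENSRNOG00000011073 (top) and ENSRNOG00000017456 (bottom) in each library by region and age, with WT in grey and KI in red; horizontal marks and bars give the mean and SD. The first is lower in KI in every region and age, by mean, and the second is higher in KI in cerebellum at 19 and 24 months.

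Whether the genotype difference itself changed between regions was tested with the animal as a block. Between striatum and cerebellum 20 genes were called for a change in the KI minus WT difference at 19 months and 1 gene at 24 months (edgeR), but 2 of 24 splits of the animals gave as many at each age, so chance is not excluded for these counts. Between cortex and cerebellum, added after the data were seen, it changed for 51 genes at 19 months and 36 at 24 months. ENSRNOG00000017456 passed in each of these 4 tests, with a KI effect lower than in cerebellum by log2 differences of -1.67 and -1.64 in striatum and -1.79 and -1.85 in cortex (edgeR adjusted p = 0.000251, p = 0.0259, p = 6.7e-08 and p = 3.08e-05). ENSRNOG00000034102 passed in 3 of them and had a log2 difference of 0.85 between striatum and cerebellum at 19 months (edgeR adjusted p = 0.00069). Between striatum and cortex 0 genes passed at 10, 19 and 24 months with edgeR, with 1085, 379 and 230 at an unadjusted p under 0.05; DESeq2 called 0, 1 and 0.

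The genotype difference was not shown to depend on sex or on age. For sex by genotype 0 genes passed with edgeR in striatum, cortex and cerebellum, with 807, 547 and 861 at an unadjusted p under 0.05, and DESeq2 called 1, 0 and 1. For age by genotype 0 genes passed with edgeR in all 5 tests. In striatum 377 genes had an unadjusted p under 0.05 between 10 and 19 months and 324 between 19 and 24 months, where chance gives 784 and 805, and DESeq2 called 9 and 0. In cortex these were 463 and 1828, where chance gives 781 and 796, and DESeq2 called 1 and 0. The second count lies above chance although no gene passed, but genes are not independent and the chance value carries no spread. The log2 differences in cortex had a Spearman correlation with transcript length of 0.363 at 19 months and -0.444 at 24 months. Whether these opposite trends raised the count was not tested, so no change with age is read from it. In cerebellum 521 had an unadjusted p under 0.05 between 19 and 24 months, where chance gives 791, and DESeq2 called 0.

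Among WT animals more genes separated the ages than separated the genotypes in striatum and cortex by count. Between 10 and 19 months 449 genes rose and 334 fell in striatum, and 600 rose and 480 fell in cortex (n = 10 per age, edgeR). With RLE factors the striatal balance turned, with 370 that rose and 414 that fell, and in cortex 577 rose and 539 fell. Between 10 and 24 months 4 rose and 0 fell in striatum, and 65 rose and 41 fell in cortex (n = 10 and n = 4). In cerebellum 108 rose and 82 fell between 19 and 24 months (n = 10 and n = 4). The 19-month animals carry identifiers of another series than those of 10 and 24 months, so in comparisons with 19 months age and animal series cannot be told apart.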

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

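The tests of cortex in the cerebellar and in the striatal dissections, the fits with the length slope or the cortex score or without single libraries for the region-enriched groups, the region-enriched groups, the averages over ages and the comparisons of cortex with cerebellum were chosen only after the results were seen.

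KI cerebellum had 352 and 334 genes called at 19 and 24 months. With edgeR and each age fitted alone, at most 3 were called in any striatal or cortical comparison. Other settings gave up to 199 in striatum, at 6 months without WT M1, where genotype and the trend with transcript length cannot be told apart. An equal response of the cerebellar genes hidden by wider spread is argued against. Over the genes called in cerebellum at 24 months, the median difference in their direction at 19 months was 3.37% of the cerebellar one in cortex and 0.443% in striatum. At 24 months the risers and fallers of cerebellum at 19 months had medians of 0.0949 and -0.0661 in striatum and 0.0247 and -0.0226 in cortex. In cerebellum these were 0.321 and -0.256. Genes that respond only in striatum or cortex are not covered, and in striatum at 24 months the simulation recovered 11 of 100 changes of 0.5. Cortex in the KI cerebellar dissections is argued against, since the median change of cortex-enriched genes was 0.0423 and 0.0763 at 19 and 24 months. Dilution by cortex large enough for the fall of the cerebellum-enriched genes would need 0.616 and 0.653. Dilution by striatum or by other tissue was not tested. The striatum-enriched genes had medians of 0.128 and -0.0568 at these ages. A trend with transcript length is argued against as the whole cause, since 637 and 400 genes were called with the length slope as a covariate. A larger effect of the knock-in in cerebellum and a change in its cell composition both stay open, since no cell type list was tested.

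In KI striatum at 24 months the striatum-enriched genes had a median log2 difference of -0.44 and the cortex-enriched genes of 0.34, and without KI M1 and M2 these were -0.283 and 0.0546, so the second rests on those libraries. With the cortex score as a covariate 61.4% of the first remained, at -0.272, so more cortex in some KI dissections may account for part of it. Over the 11 libraries the scores had Pearson r = -0.777 (permutation p = 0.0034) and Spearman rho = -0.5 (permutation p = 0.121), with r = -0.57 without KI M2 and KI M1 and r = -0.815 within the 7 KI libraries. A trend with transcript length is argued against, since 129% remained with the length slope as a covariate. Loss of striatal transcripts in KI and uneven dissection cannot be told apart here, because the libraries with the highest cortex scores, M1 and M2, are both KI.

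Single libraries lay apart from their group in 4 of 58 tests, each of 1 measure in 1 group, where chance gives about 1 in 20, or 2.9. The tests use the same libraries for several measures, so they are not independent. ENSRNOG00000017456 stood at 3.68 CPM in WT cerebellum M1 at 19 months, with the nearest other library at 2.63. The mean log2 CPM of cortex-enriched genes was 2.86 in WT cortex F4 at 19 months and 3.08 in WT cortex M1 at 24 months. The mean log2 CPM of striatum-enriched genes was 2.46 in KI striatum F4 at 19 months.

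The genotype difference itself was compared between regions. Between striatum and cerebellum 20 genes were called at 19 months and 1 at 24 months, and in each case 2 of 24 splits gave as many, with up to 175 and 6 genes in the others, so chance is not excluded. Between cortex and cerebellum it differed for 51 and 36 genes, and only the real one of 24 splits gave as many at each age. The others gave at most 0 genes. These values argue against chance, but 24 splits can give no share below 1 of 24.

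Other splits of the same libraries that kept the number of each sex per group were counted for each comparison, the real one included. The share therefore cannot fall below 1 in the number drawn, and the shares were not adjusted over comparisons. For cerebellum at 19 months only the real one of 100 splits gave as many as 352 genes, with at most 1 in the others, which argues against chance. At 24 months only the real one of 100 gave as many as 334 genes. The others reached 178 there, above the 115 called without WT M2. With 150 possible splits another split can keep most of the real grouping. How much of it the split with 178 genes kept was not examined, so genotype and another structure of the samples cannot be told apart there. For striatum at 10 and 19 months 2 of 60 splits gave at least 1 and 3 genes, the real one among them. The others reached 1870 and 304 genes, which points to a structure of the samples apart from genotype. By the rule fixed before the data were examined, 2 of 60 counts against chance. Because of the higher counts in other splits chance is not taken as excluded here, which departs from that rule. With a real count of 0 every split gives as many, so the count of splits decides nothing for striatum at 24 months (60 of 60, at most 2385) or cortex at 10, 19 and 24 months (80 of 80 each, at most 3427, 3530 and 1336), where the large counts point to such structure too. At 2 and 6 months 10 splits are too few: 10 gave at least 0 genes, with at most 16, and 1 gave at least 2, with at most 1. Averaged over ages, only the real one of 40 splits gave as many as 4 genes in striatum, 5 in cortex and 1056 in cerebellum. The others gave at most 1, which argues against chance as far as 40 splits can show.

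The count of splits also decides nothing for the 0 genes of sex by genotype, where 24 of 24 necessarily gave as many, with at most 50 in striatum, 3 in cortex and 1 in cerebellum. The same holds for age by genotype, with at most 0 and 961 in striatum, 0 and 1 in cortex and 1 in cerebellum, and for striatum against cortex, with at most 0, 0 and 169 at 10, 19 and 24 months. For age in WT animals only the real one of 60 splits gave as many as 783 genes in striatum, 1080 in cortex and 190 in cerebellum. The others gave at most 196, 543 and 1, which argues against chance. Between 10 and 24 months 2 of 60 gave as many as 4 genes in striatum (at most 12) and 106 in cortex (at most 1520, which points to a structure of the samples). By the rule fixed before the data were examined, both shares count against chance. Because other splits gave higher counts, chance is not taken as excluded for these 2 counts, which departs from that rule.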

How the results depend on the processing

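The fits with the length slope, with the cortex score, without outlying libraries, of cortex against cerebellum and averaged over ages were added after the data were seen, as was leaving out libraries for the region-enriched groups. Of the counts under an alternative 196 stayed close to the reported count and 84 differed by more than 1.5 times, among them the overlap of cerebellar calls, at 57 genes with an adjusted p under 0.01 and 263 with DESeq2 against 139; the cause was not tested for these except where fewer samples were used. The tests of gene lists fixed before the data were examined were not run, so their alternatives were not run either. With DESeq2 genotype counts were 15, 105, 2, 5 and 2 in striatum at 2, 6, 10, 19 and 24 months, 17 and 4 in cortex at 10 and 24 months, and 548 and 668 in cerebellum at 19 and 24 months. DESeq2 called 1 gene for sex by genotype in striatum and in cerebellum, 9 and 1 for age by genotype between 10 and 19 months in striatum and cortex, and 1 between striatum and cortex at 19 months. It called 65 and 29 genes between striatum and cerebellum, 139 and 153 between cortex and cerebellum, and for age in WT 1379 and 46 in striatum, 533 in cortex between 10 and 24 months and 698 in cerebellum. With all libraries of a region in 1 fit the counts were 0, 81 and 1 in striatum at 6, 10 and 24 months and 2 in cortex at 24 months. Without a count filter 6 genes were called in striatum at 6 months and 1 in cortex averaged over ages, and with the strict filter 1 at 6 months. Limma-trend called 0 genes in striatum at 10 and 19 months with each pseudocount and without its filter, and 6 at 6 months without its filter. It moved the median of all genes by 0.11 in striatum at 24 months. With the length slope 1 gene was called in striatum at 6 months, 3, 1 and 1 in cortex at 10, 19 and 24 months, and 637 in cerebellum at 19 months. With the cortex score 4 were called at 6 months, and the median of cortex-enriched genes in striatum at 24 months came to -0.0244, near 0 by construction, since the score is made from these genes; without it that group's camera p was 0.181 with an estimated correlation, against 9.45e-10 with the preset one. Without outlying libraries 3 were called at 2 months. Leaving out 1 library at a time at 24 months gave medians from -0.514 to -0.342 for striatum-enriched and from 0.202 to 0.443 for cortex-enriched genes in striatum, and from -0.106 to -0.0932 for cerebellum-enriched genes in cerebellum. Without KI M1 and M2 the cortex-enriched genes came to 0.0546 (camera p = 0.401).

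In females alone 0 and 1 genes were called in striatum at 10 and 19 months, 1 in cortex at 24 months, and 77 and 27 in cerebellum at 19 and 24 months. In males alone these were 0 and 0 in striatum at 10 and 19 months, 1 in striatum at 24 months, and 8 and 60 in cerebellum. Fewer samples were used in each. Without 24 months 1 gene was called for sex by genotype in cerebellum. Without the animal as a block 83 and 70 genes were called between cortex and cerebellum at 19 and 24 months. At an adjusted p under 0.01 the overlap of striatal calls between ages was 0 genes, against 1. With RLE factors the 783 genes of age in WT striatum at 19 months became 784, of which 370 rose and 414 fell, against 449 and 334. Leaving out 1 library at a time gave 0 to 36 genes in striatum at 2 months and 1 to 199 at 6 months, 0 to 0 in striatum and in cortex at 24 months, and 115 to 338 in cerebellum at 24 months. The libraries that moved a count by more than 1.5 times were KI M2 and M3 and WT M1, M2 and M3 at 2 months, KI M1, M2 and M3 and WT M1 and M2 at 6 months, and KI M4 and WT F1, M1 and M2 in cerebellum.

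With the replicate number as a block 1, 5, 0 and 0 genes were called in striatum at 2, 6, 10 and 19 months, 199 and 159 in cerebellum at 19 and 24 months, and 3 for sex by genotype in striatum. For age in WT the block gave 377 and 0 in striatum, 371 in cortex between 10 and 19 months and 4 in cerebellum. Same-number libraries were not taken as pairs: in 0 of 10 comparisons did all pairs correlate above 0.1, with medians from -0.177 to 0.138. The highest median was at 2 months, where same-number libraries share the first part of their animal identifiers. There the pairs correlated from 0.0704 to 0.201, against a median of -0.079 for other pairs, so pairing at that age is not excluded. ENSRNOG00000011073 passed in 9 of 15 alternatives in striatum at 10 months and in 9 of 15 at 19 months, with log2 differences from -0.55 to -0.38 and from -0.60 to -0.51 and adjusted p up to 1. ENSRNOG00000023148 passed in 9 of 15 at 19 months, from 0.51 to 0.64. Neither passed with limma-trend, the block or single sexes. In cerebellum at 19 months ENSRNOG00000011073 had adjusted p = 0.0731 in females and p = 0.106 in males with edgeR, and it passed in 12 of 14 alternatives.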

Other observations

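Following the cerebellar calls in other regions was chosen only after the results were seen, as was removing the trend with transcript length.

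The genes called in KI cerebellum at 19 months were also followed in the other regions. In KI striatum at 24 months 94 of 151 risers were above 0 and 120 of 189 fallers below 0, with median log2 differences of 0.09 and -0.07 against 0.34 and -0.28 in cerebellum. With an estimated correlation the camera adjusted p was 0.538 and 0.105, over 36 tests. In KI cortex at 19 months 84 of 150 risers and 122 of 182 fallers kept their sign, with medians of 0.01 and -0.03 and adjusted p of 0.761 and 0.515 with an estimated correlation. Over the 8 striatal and cortical comparisons the share with the same sign ran from 46% to 64% for risers and from 39.2% to 67% for fallers, lowest in cortex and in striatum at 10 months, and none passed with an estimated correlation. With the preset correlation the camera adjusted p in striatum was 0.0197 for risers and 0.0413 for fallers at 19 months. At 24 months these were 0.025 and 0.00632. In cortex it was 0.025 for fallers at 19 months and 0.0458 for risers at 24 months, and the remaining tests did not pass.

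Fold changes of the 10 genotype comparisons were correlated across genes, which are not independent replicates, with Spearman rho from -0.599 to 0.612 over 45 pairs. A trend with transcript length was tested as the cause: the mean absolute rho was 0.218 before and 0.178 after the trend was removed, so 81.4% remained. The trend is argued against as the whole cause, and what else the comparisons share was not tested.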
